A study of Dehalococcoides mccartyi 195 with 53 samples.

How the data were processed

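RNA of 53 subcultures of a mixed community holding Dehalococcoides mccartyi was measured on two-colour Agilent arrays, with the culture in Cy5 and a common pool in Cy3, per the labels. The pool came from the main reactor after 3 days without feeding, per the labels. Each array has 1 dye orientation, so dye effects specific to a gene cannot be separated from the ratio to the pool. They are shared by all arrays and drop out of comparisons between groups.

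Per the file headers, 53 scanner files were made with Feature Extraction 10.5.1.1. They hold spot and local background values as intensity, on a linear scale, for both channels. They also hold processed signals of both channels, which the authors' software corrected for background and dye, and their ratio on a log10 scale, per the file headers. A deposited table of log10 ratios averaged over the spots of each probe and a deposited table of Cy5 intensity, both made by the authors, cover the same arrays. Of the 53 columns in the ratio table, 7 matched the scanner values of another array better than those of the array in their name, and of those in the intensity table, 10 did. In the ratio table these columns are the 4 of dCP feeds A and B and the 3 of unfed cultures, and in the intensity table also the 3 of PHB. Which source is wrong is not known, so the names of single arrays in these groups are uncertain. The scanner files were used for the results, and the ratio table as an alternative. dCP feeds A and B stand together on 1 side in every comparison, as do the unfed arrays. Labelling was of amino-allyl cDNA, per the labels. Whether amounts of labelled cDNA were made equal between arrays is not given in the sources used here.

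Median spot values were corrected with the normexp method (offset 50), converted to log2 Cy5/Cy3 ratios, and normalized within each array by loess in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). These log2 ratios were computed here from the deposited intensities. No normalization between arrays was applied. The offset pulls ratios of dim spots toward 0, so folds of dim probes are compressed. Where a probe was not well above background in Cy5 on any array of a side, the difference is given as at least N-fold. That is the mean of the brighter side over the dimmer one, each dim array at the higher of its own signal and the lowest signal well above background (Cy5 channel after loess and Aquantile). These bounds rest on Cy5 alone, without the ratio to the pool, so fitted folds can lie below them, and they are open to dye effects that vary between arrays. The adjusted p beside them is that of the fitted ratio. Each array holds 15208 spots other than controls, for 1627 probe names, most often 9 spots per name (1257 names, range 9 to 25). Spots that the software marked as outliers, 2.63% to 7.33% per array, were left out, and the mean over the other spots of a name was used. A name was kept when well above background in Cy5 or Cy3 on at least 2 arrays. That left 1551 names for testing, 1438 of them with a DET number, the locus tag of D. mccartyi. It left out 75 names, and a luciferase spike was left out too. "Genes" below means these probe names, which include community sequences and tRNA.

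The median Cy5 spot signal above background was 80 scanner units over the arrays (range 8 to 988) and the median Cy3 signal 58 (1 to 99). Between 19.8% and 92.8% of spots were well above background in Cy5. The number of arrays, 2 or 3 per group, limits the precision of every value.

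Groups were taken from the labels. Group means were fitted on all 53 arrays with limma (lmFit, eBayes), and each comparison is a difference of means, pooled over feeds where several groups stand on a side. The rate slope was fitted on the 18 feed arrays with acceptor as covariate and log2 respiration rate as the variable. The bend is the step from feed C to B minus that from B to A, each per doubling of the rate and averaged over acceptors, and the acceptor by rate interaction is a limma F test of different slopes. All tests are two-sided, adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors beside fitted log2 values are standard errors, and those beside group means are standard deviations. Correlations across arrays or groups carry permutation tests with 1e+05 permutations.

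Lists of genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over lists and comparisons. Of 21 lists, 8 have members here: catalytic subunits of reductive dehalogenases (rdhA, 15 of 19 tested), the Hup (3), Ech (8), Hym (7) and Vhu (3) hydrogenases, the Nuo complex (11), a molybdopterin oxidoreductase annotated as formate dehydrogenase (3), and community members other than D. mccartyi (6). Tags were assigned to lists by hand, from knowledge of the published annotation of D. mccartyi, and were not checked against an annotation file, so list counts and set tests rest on that assignment. The other 13 lists rest on product names, which the probes do not carry, and were not evaluated. Product words were read with case, since without it hydrogenase probes named NiFe entered the nitrogen list. Of the community list 4 members lack values on some arrays, so its set test rests on 2 Syntrophomonas probes of 6 members. A further 7 lists were added after the files were seen: tRNA (41), ribosomal RNA (3), community clone (40), MHU-ending (5), methanogen clone (3) and Syntrophomonas clone probes (5), and the most spotted protein loci (13). They were adjusted as a family of their own. Values missing on some arrays kept the methanogen clone list out of the set test, and left 2 of 5 Syntrophomonas probes and 18 of 40 community clone probes in it (22 for the rate slope).

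The genes named are the 10 with the largest rise and fall among those past the threshold in the rate slope, PCE fed against unfed, dCE against PCE, TCE against PCE, dCP against PCE feed C and PCE high against PCE low, and 3 each elsewhere. Members of the rdhA, hydrogenase, Nuo and formate dehydrogenase-like lists are named in any comparison. Outside the lists at most 2 rising and 2 falling tags are printed, since the files pair no names with tags. Comparisons, tests, lists, this rule and most alternatives were set before the data were examined. Alternatives and lists added later are named as such.

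Alternatives covered the software's own ratios, median centring, scale normalization between arrays, Cy5 alone with quantile normalization, filters on dim probes, the authors' ratio table, blocks for replicate number and slide, other comparators, fits on fewer arrays and leaving out each array. The arrays lie on 7 slides scanned on 2 days. PCE, TCE and dCE feeds lie on slides 4, 5 and 6, so acceptor and slide coincide for them, while rates vary within each slide. Replicate numbers pair no samples: over 49 pairs of groups, residuals of equal numbers correlated with a median r of 0.0339 (range −0.571 to 0.741).

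The fits were tested on simulated data with 200 changed genes. A log2 change of 1 was found for 67.2% of genes in PCE high against PCE low and for 53.7% in lactate against butyrate, and a change of 2 for 97% in both. A slope of 0.3 per doubling was found for 88.1% of genes, and different slopes between acceptors of 0.3 for 50.7%. Plots were drawn with matplotlib 3.10.9.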

Results

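The 53 arrays compare cultures of a mixed community against a common starved pool. The community holds Dehalococcoides mccartyi, a bacterium that uses hydrogen to respire chlorinated compounds, together with fermenters and methanogens. Acceptors were tetrachloroethene (PCE), trichloroethene (TCE), dichloroethene (dCE) and dichlorophenol (dCP). The isomers of dCE and dCP are not given in the sources used here. The cultures fall into 24 groups, 19 of 2 arrays and 5 of 3 arrays (PCE high, PCE low, PHB, dCE inhibited and unfed). PCE, TCE and dCE were each fed at 3 rates, with respiration of 18 to 34 µeeq per litre and hour in feed A, 4.5 to 8.9 in feed B and 0.9 to 2.3 in feed C. A µeeq is a microequivalent of electrons. In H2 only replicate 2, PCE feed B replicate 1, PCE feed C replicate 2 and dCE feed C replicate 2 the Cy3 median was only 1 to 3. Ratios of these 4 arrays had SDs of 0.18 to 0.406, against 0.311 to 1.6 on the others. Replicates correlated across genes with r from 0.258 in dCE feed C to 0.984 in PCE high, and genes are not independent replicates.

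How transcripts follow the respiration rate was asked over the 18 feed arrays. With each acceptor the ratio of donor to acceptor fell from feed C to feed A, per the labels. Rate and this ratio therefore cannot be told apart in the feeds. DET0079 (tceA, the reductive dehalogenase of TCE) rose 1.81-fold with each doubling of the rate (log2 0.85, SE 0.14, adjusted p = 0.00207). Its log2 ratio to the pool was −0.25 ± 0.07 (SD, n = 2) in PCE feed C and 4.68 ± 0.79 in PCE feed A, against −0.37 ± 0.08 (n = 3) in unfed cultures, where it was not well above background. Among the 15 reductive dehalogenases tested, 2 rose, DET0079 and DET0162 (0.29, SE 0.08). Another 5 fell, among them DET1545 by 0.54 (SE 0.18, adjusted p = 0.0193), DET1535 by 0.30 (SE 0.08), and DET0173 by 0.42 (SE 0.14, adjusted p = 0.02), whose slope was 0.01 after scale normalization. The other 8 did not pass, DET0318 (pceA, the reductive dehalogenase of PCE) with 0.15 (SE 0.15, adjusted p = 0.389). Counts adjusted over the list alone were 2 and 5. The call of DET1545 was lost without PCE feed A replicate 1 (−0.49) or TCE feed A replicate 1 (−0.47), and that of DET0173 without dCE feed A replicate 2 (−0.34).

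Several members of the hydrogenase and formate dehydrogenase-like lists rose with the rate. The molybdopterin oxidoreductase list rose in all 3 members, DET0186 by 0.56 per doubling (SE 0.12) and DET0187 by 0.51 (SE 0.11, adjusted p = 0.00321). Of the Hup uptake hydrogenase DET0111 rose by 0.56 (SE 0.10) and DET0112 by 0.40 (SE 0.10), while DET0110 (hupL, the large subunit) had 0.27 (SE 0.11, adjusted p = 0.0523). Adjusted over the list alone, all 3 Hup members passed. The Hym list rose in 6 of 7 members, such as DET0145 (0.42, SE 0.10) and DET0147 (0.40, SE 0.08), and the Nuo list in 5 of 11. The Ech list rose in 7 of 8 members and fell in DET0860, by 0.28 (SE 0.05). Counts adjusted over the list alone were the same for these 4 lists. None of the 3 Vhu and none of the 6 community members passed the limma test. Of the 8 lists set before, none passed camera, Hym coming nearest (adjusted p = 0.0515).

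**Figure D1:**
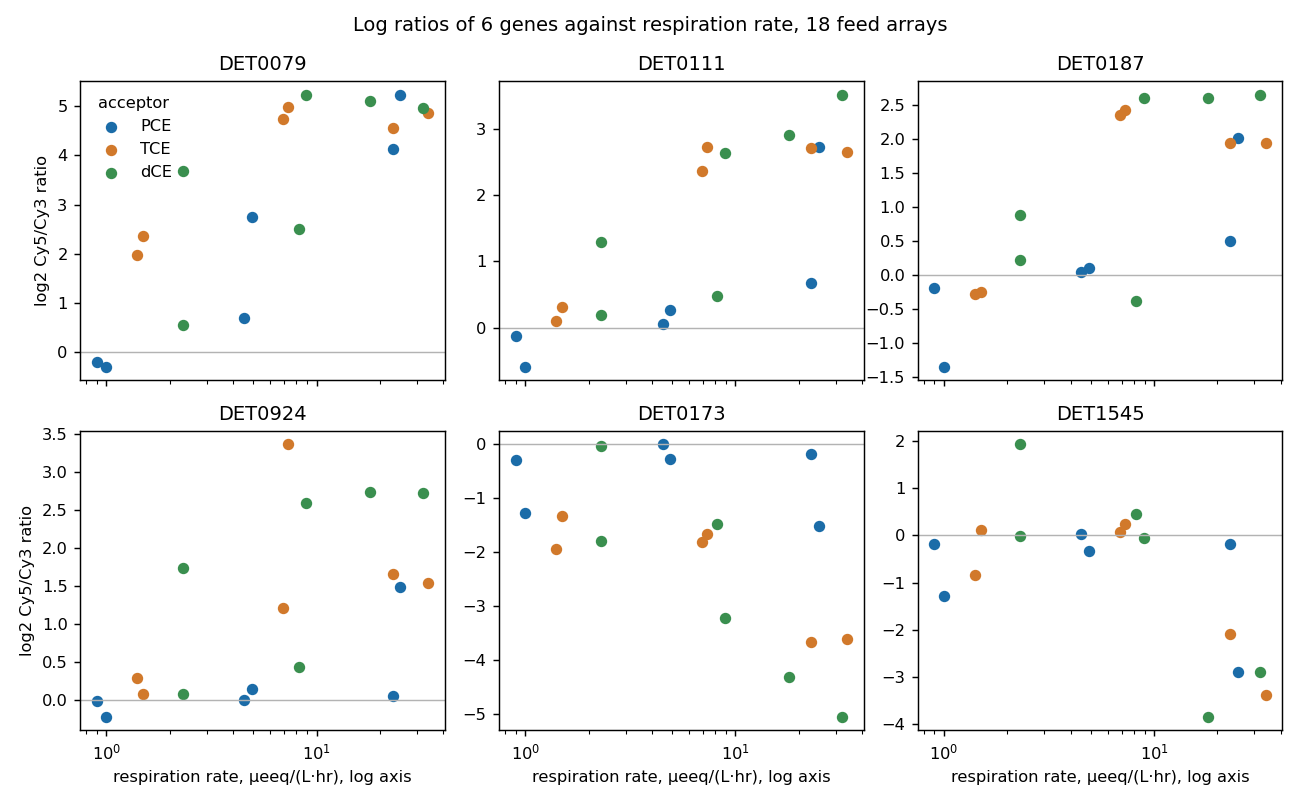
Log2 Cy5/Cy3 ratios of 6 genes in the 18 feed arrays against respiration rate in µeeq per litre and hour on a log axis, with a point per array and colour for the acceptor. DET0079, DET0111 and DET0187 lie higher at high rates, while DET1545 and DET0173 lie lowest in the fastest TCE and dCE feeds.

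In limma the rate slope was called for 837 of 1551 genes, 428 upward and 409 downward, and 941 had an unadjusted p under 0.05. The steepest outside the lists included DET0650 (0.82 per doubling, SE 0.12) and DET0476 (0.73, SE 0.15) upward, and DET1322 (−0.94, SE 0.20) and DET0955 (−0.80, SE 0.13) downward. After median centring the split was 376 to 73. Within 1 acceptor, and so within 1 slide, TCE alone gave 316 genes. PCE alone gave 0 genes in limma (141 unadjusted) and dCE alone 0 (520 unadjusted). The slope of DET0079 was 1.07 per doubling with PCE (SE 0.15, adjusted p = 0.246), 0.61 with TCE (SE 0.15, adjusted p = 0.0415) and 0.85 with dCE (SE 0.36, adjusted p = 0.162). DET0173 had −0.02 with PCE (SE 0.13, adjusted p = 0.911), −0.45 with TCE (SE 0.12, adjusted p = 0.0485) and −1.10 with dCE (SE 0.23, adjusted p = 0.106). DET1545 had −0.19 (SE 0.22, adjusted p = 0.576), −0.55 (SE 0.22, adjusted p = 0.13) and −1.17 (SE 0.34, adjusted p = 0.106) in the same order. With replicate number as a block 845 genes were called.

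Arrays of fast cultures were also brighter in Cy5. Over the 47 arrays with a stated rate, log2 rate and log2 Cy5 brightness correlated with r = 0.723 and rho = 0.7 (permutation p = 1e-05 for both, the smallest the permutations can give; adjusted p = 3.5e-05 over 7 relations). Without the 2 farthest arrays r was 0.681. On scan day 1 r was 0.508 and rho 0.5 (20 arrays; permutation p = 0.0236 and 0.0265, adjusted 0.0413 and 0.0464; r = 0.365 without 2). On scan day 2 r was 0.829 and rho 0.838 (27 arrays; permutation p = 1e-05, adjusted 3.5e-05; r = 0.785 without 2). Over the 18 feed arrays r was 0.601 and rho 0.658 (permutation p = 0.00875 and 0.00357, adjusted 0.0204 and 0.00833), and 0.427 without 2. Within slides 4, 5 and 6, 6 arrays each, r was 0.584, 0.6 and 0.707 and rho 0.714, 0.771 and 0.812 (exact permutation p = 0.211, 0.213 and 0.111 for r and 0.137, 0.102 and 0.0717 for rho). Adjusted values were 0.213, 0.213 and 0.155 for r and 0.137, 0.119 and 0.1 for rho. Without 2 arrays r fell to 0.0465, 0.299 and 0.372 on these slides. With log2 brightness in the rate model, limma called 0 genes (352 at an unadjusted p under 0.05). The slope of DET0079 was then 0.78, that of DET0111 0.37 and that of DET0187 0.32.

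**Figure D2:**
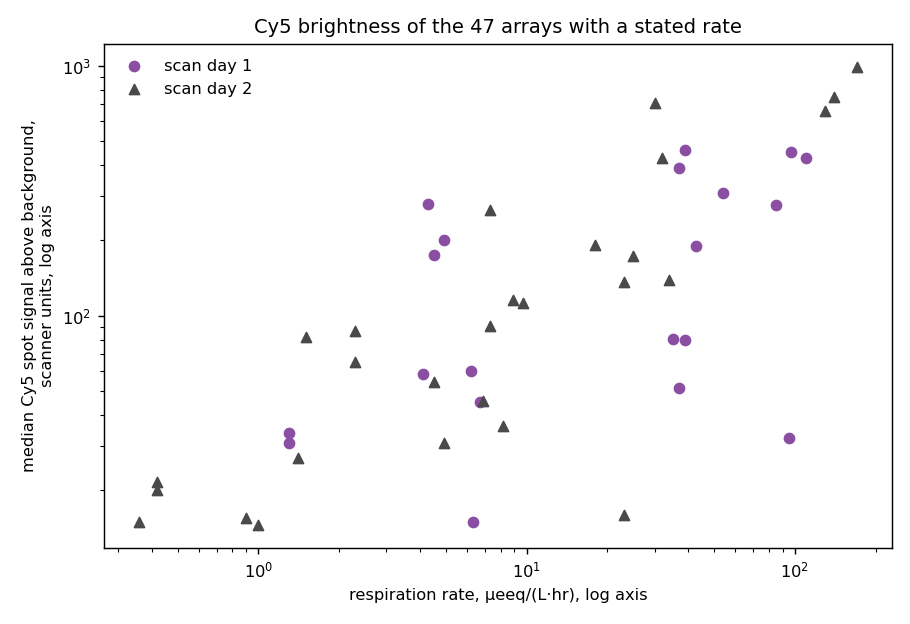
Median Cy5 spot signal above background, in scanner units on a log axis, against respiration rate in µeeq per litre and hour on a log axis, with 1 point per array and shapes for the 2 scan days. Brightness rose with the rate over the 47 arrays (r = 0.723 on log scales).

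The series title names a transition point related to respiration rate, so both steps between feeds were tested, each with 6 arrays a side. In feed B vs feed C, DET0079 rose 4.4-fold (log2 2.14, SE 0.46, adjusted p = 0.0107), DET0187, well above background on 3 of 6 arrays of feed C, 2.56-fold (1.36, SE 0.32, adjusted p = 0.0161) and DET0111 2.33-fold (1.22, SE 0.31, adjusted p = 0.0205). All 3 Hup members rose (camera adjusted p = 0.0115; adjusted p = 0.747 with an estimated correlation), as did 2 of 3 of the formate dehydrogenase-like list (0.025; 0.747). The Hym list rose in 2 of 7 members, 4 adjusted over the list alone (0.0226; adjusted p = 0.82 with an estimated correlation), and the Nuo list in 1 of 11, 3 adjusted over the list alone (0.00253; 0.763). DET1559 (1.43, SE 0.47, adjusted p = 0.059), DET1545 (0.12, SE 0.47) and DET0180 (0.49, SE 0.35) did not pass. Of the 15 reductive dehalogenases 2 rose, DET0079 and DET0318, against 3 adjusted over the list alone. In total 58 genes were higher and 37 lower (424 unadjusted), with splits of 136 to 153 for Cy5 alone, 241 to 281 in the authors' table and 0 to 1 after median centring. The calls rest on single arrays. DET0079 had 1.80 without PCE feed B replicate 2, 2.12 without PCE feed C replicate 1, 2.09 without TCE feed B replicate 2 and 1.68 without dCE feed B replicate 1, each no longer called. DET0187 lost its call without the last 3 of these (1.16, 1.34 and 0.86), and DET0111 without all 4 (1.19, 1.15, 1.16 and 0.86) and without dCE feed C replicate 2 (1.04). The count was 16 without PCE feed B replicate 2, 3 without PCE feed C replicate 1, 148 without PCE feed C replicate 2, 171 and 5 without TCE feed B replicates 1 and 2, 34 without TCE feed C replicate 1, 63 without TCE feed C replicate 2, 1 and 454 without dCE feed B replicates 1 and 2, and 57 without dCE feed C replicate 2. On the arrays compared alone it was 0 in limma (277 unadjusted). With brightness in the model it was 33, and with slide as a block 111.

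In feed A vs feed B several reductive dehalogenases fell. DET1545 fell to 0.163 of its level (log2 −2.61, SE 0.47, adjusted p = 0.000875), DET0173 by 1.65 on the log2 scale (SE 0.42, adjusted p = 0.0119) and DET0180 by 1.57 (SE 0.35, adjusted p = 0.00658). In feed A the mean of DET1545 was −2.73 ± 0.91 (n = 2) with TCE and −3.36 ± 0.66 with dCE, against 0.16 ± 0.12 and 0.19 ± 0.37 in feed B. With PCE it was −1.54 ± 1.91 against −0.15 ± 0.25. It was well above background on 3 of 6 arrays of feed A. Of the rdhA list 2 rose and 5 fell, the same adjusted over the list alone. The Hym list rose in 6 of 7 members, such as DET0147 (1.05, SE 0.22), with camera adjusted p = 0.00744 (adjusted p = 0.747 with an estimated correlation). DET0111 rose by 1.11 (SE 0.31, adjusted p = 0.0156), but had −0.13 after scale normalization. DET0079 had 1.32 (SE 0.46, adjusted p = 0.0436), turning to −10.60 after scale normalization, and DET1559 −0.10 (SE 0.47, adjusted p = 0.897). In total 200 genes were higher and 108 lower (613 unadjusted), with 283 to 246 in the software's own ratios, 301 to 252 in the authors' table and 200 to 13 after median centring.

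Single arrays decided much of feed A vs feed B as well. DET0079 lost its call without PCE feed A replicate 1 (1.14), PCE feed B replicate 1 (0.98), TCE feed A replicate 1 (1.27), TCE feed B replicate 1 (1.28) or 2 (1.37), dCE feed A replicate 1 (1.30) or 2 (1.35), or dCE feed B replicate 2 (0.87). DET0173 lost it without PCE feed A replicate 1 (−1.42) or dCE feed B replicate 2 (−1.35), as did DET0111 (0.77 and 0.75). The count was 22 and 642 without PCE feed A replicates 1 and 2, 178 without PCE feed B replicate 1, 121 without TCE feed A replicate 1, 149 without TCE feed B replicate 1, 160 without dCE feed A replicate 2, and 636 and 16 without dCE feed B replicates 1 and 2. On the arrays compared alone it was 0 in limma (318 unadjusted), with brightness in the model 62 and with slide as a block 397. DET1545 kept its call without each array, and had −2.61 on the arrays compared alone, not called there.

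In the bend of the rate response, the change per doubling from C to B differed from that from B to A for 0 of 1542 genes in limma (103 unadjusted). Other settings called some: 79 genes after scale normalization, 11 in Cy5 alone, 9 in the software's own ratios, 6 with a slide block, 5 in the authors' table, 4 with brightness in the model, 3 with a strict filter, 2 without arrays of dark reference and 1 with a replicate block. Without single arrays the count was 10 (PCE feed A replicate 2 or dCE feed C replicate 1), 7 (TCE feed A replicate 1), 5 (PCE feed C replicate 2), 3 (dCE feed B replicate 2), 2 (PCE feed B replicate 1 or TCE feed B replicate 2) or 1 (PCE feed B replicate 2). The reductive dehalogenases as a list had a positive bend, their change per doubling being lower from B to A than from C to B (median difference 0.28 log2 per doubling, 0 members over all genes, 3 adjusted over the list alone; camera adjusted p = 0.0004, adjusted p = 0.138 with an estimated correlation). Slopes that differ between acceptors were found for 0 of 1551 genes (limma F test, 109 unadjusted), and for 1 without PCE feed C replicate 1 or dCE feed B replicate 2.

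The chlorinated ethenes differ in their number of chlorine atoms, and each was fed at 3 levels (6 arrays per acceptor). Respiration differed within levels: in feed C it was 1 and 0.9 µeeq per litre and hour with PCE, 1.5 and 1.4 with TCE and 2.3 with dCE. Feeding lasted 96 h, except 48 h in TCE feed A replicate 2 and dCE feed A replicate 2. DET0079 was 3.63-fold higher with TCE than with PCE (log2 1.86, SE 0.46, adjusted p = 0.00437) and 3.06-fold higher with dCE (1.62, SE 0.46, adjusted p = 0.0137). Scale normalization turned both (−17.86 and −17.73), and in feed A alone the differences were 0.03 and 0.35. DET0318 did not pass with TCE (−0.13, SE 0.32, adjusted p = 0.8, interval −0.78 to 0.52) or dCE (0.65, SE 0.32, adjusted p = 0.119, interval 0.01 to 1.30). In feed A alone DET0318 was lower with TCE, by 2.17, and passed. DET0173 was lower with TCE (−1.75, SE 0.42) and with dCE (−2.06, SE 0.42, adjusted p = 0.00146). Of the rdhA list 2 rose and 1 fell with TCE, and 1 rose and 2 fell with dCE, the same adjusted over the list alone.

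All 3 Hup members were higher with TCE (camera adjusted p = 0.0515) and with dCE (0.0162; adjusted p = 0.747 with an estimated correlation). DET0111 differed by 1.31 (SE 0.31, adjusted p = 0.00294) and 1.34 (SE 0.31, adjusted p = 0.00361), turning to −0.84 and −0.76 after scale normalization. Of the 7 Hym members 5 were higher and 1 lower with TCE (0.0466; adjusted p = 0.82 with an estimated correlation). With dCE 6 were higher (0.000307; adjusted p = 0.704 with an estimated correlation), such as DET0145 by 1.74 (SE 0.35, adjusted p = 0.00129). Of the 11 Nuo members 2 were higher with TCE and 5 with dCE, 8 adjusted over the list alone (0.0165; adjusted p = 0.82 with an estimated correlation). In the community list 2 members were higher with TCE and 2 lower (0.0226; adjusted p = 0.747 with an estimated correlation) in a set test of 2 of its members; its median was −0.19. Its probe 11_DCL2_Syntrophomonas_sp, from a bacterium that ferments fatty acids, was 3.32-fold higher with TCE than with PCE (log2 1.73, SE 0.27, adjusted p = 7.15e-05), turning to −0.51 after scale normalization. The hydrogenase probe DCL2_Hyd_MvH1-MHU was lower with TCE (−2.49, SE 0.47) and with dCE (−2.76, SE 0.47), well above background there on 4 and 2 of 6 arrays. Its means passed 1 in PCE feeds alone, 3.00 ± 2.43 (n = 2) in A, 1.83 ± 2.21 in B and 3.62 ± 2.97 in C, so that its replicates differed as much as the groups.

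Called genes were 417 for TCE vs PCE (210 higher, 207 lower; 606 unadjusted; 99 to 41 after median centring), among them DET0297 (2.00, SE 0.61, −1.82 after scale normalization). For dCE vs PCE they were 352 (174 and 178; 633 unadjusted), DET0297 among them with 2.80 (SE 0.61; −0.75 after scale normalization). For dCE vs TCE they were 3 genes, all lower with dCE (164 unadjusted): DET0624 (−1.22, SE 0.26, adjusted p = 0.0284), DET0627 (−0.83, SE 0.13, adjusted p = 0.000447) and 1 clone probe. In Cy5 alone 30 were higher and 20 lower with dCE. No difference between dCE and TCE was found for DET0079 (−0.24, interval −1.19 to 0.70), DET0145 (0.50, interval −0.21 to 1.21) or DET0111 (0.03, interval −0.60 to 0.66), intervals that leave differences of over 2-fold open for the first 2 genes. The Hym list was ranked higher with dCE than with TCE, with 0 members over all genes, 2 adjusted over the list alone (0.0115; adjusted p = 0.763 with an estimated correlation). With slide as a random block TCE kept 14 calls and dCE 6, and with brightness in the model 168 and 70. With rate as a covariate on the 18 arrays they were 103 and 45.

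Single arrays moved these counts. TCE vs PCE gave 654 and 188 genes without PCE feed A replicates 1 and 2, 253 without PCE feed C replicate 1 and 198 without TCE feed B replicate 2. For dCE vs PCE it was 714 and 148 without PCE feed A replicates 1 and 2, 232 without PCE feed B replicate 1, 196 without PCE feed C replicate 1, 100 and 646 without dCE feed B replicates 1 and 2, and 143 without dCE feed C replicate 1. For dCE vs TCE it was 56 without TCE feed A replicate 1, 1 without TCE feed A replicate 2, TCE feed B replicate 2 or dCE feed A replicate 1, 12 without TCE feed C replicate 2, 7 and 16 without dCE feed B replicates 1 and 2, and 6 and 14 without dCE feed C replicates 1 and 2. DET0079 was no longer called for dCE without PCE feed A replicate 2 (1.43), PCE feed B replicate 1 (1.27), dCE feed B replicate 1 (1.16) or dCE feed C replicate 1 (1.09). DET0297 was no longer called for TCE without PCE feed A replicate 2 (1.63), PCE feed B replicate 1 (1.73) or TCE feed B replicate 2 (1.90). DET0624 had values from −0.96 to −1.24 without TCE feed A replicate 2, TCE feed B replicate 2, TCE feed C replicate 1, or dCE feed A replicate 1 or 2, none called.

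Dichlorophenol is an aromatic acceptor. It was set against the slowest PCE feed (dCP vs PCE feed C, 4 arrays against 2), respiration being 0.36 to 0.42 µeeq per litre and hour against 0.9 and 1. DET0318 (pceA) was 6.75-fold higher with dCP (log2 2.75, SE 0.48, adjusted p = 0.00038) and its neighbour DET0319, not well above background in PCE feed C, at least 12-fold (adjusted p = 0.00259). DET1559 (2.48, SE 0.71, adjusted p = 0.0325) was higher too, as was DET1171, well above background on 2 of 4 arrays with dCP and none of PCE feed C (at least 1.06-fold, adjusted p = 8.19e-09), so that 3 of 15 reductive dehalogenases rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.00651, adjusted p = 0.447 with an estimated correlation). DET0079 (1.43, SE 0.69, adjusted p = 0.336) and DET1535 (adjusted p = 0.221; not well above background in PCE feed C) did not pass. Of 40 community clone probes 8 were higher and 2 lower. Sulfurospirillumkb1 was 9.06-fold higher (3.18, SE 0.72) and DCL2_Hyd_MvH1-MHU, not well above background with dCP, was at least 21.4-fold lower (adjusted p = 0.00152), but had 0.20 on the log2 scale when PCE H2 of the same slide was the comparator. In total 51 genes were higher and 37 lower (222 unadjusted), with 121 to 208 in the software's own ratios, 114 to 207 in the authors' table, 97 to 143 after scale normalization and 0 to 28 after median centring. A random block for slide left 16. Without PCE feed C replicate 1 DET0318 (2.06), DET0319 (1.92) and DCL2_Hyd_MvH1-MHU (−1.45) lost their calls, and without PCE feed C replicate 2, of dark reference, Sulfurospirillumkb1 (2.63). DET1559 had 2.07 to 2.88 without PCE feed C replicate 1 or 2, dCP feed A replicate 1, or dCP feed B replicate 1 or 2, none called. The count was 20 and 56 without PCE feed C replicates 1 and 2, 43 without dCP feed A replicate 1, and 58 and 51 without dCP feed B replicates 1 and 2.

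**Figure D3:**
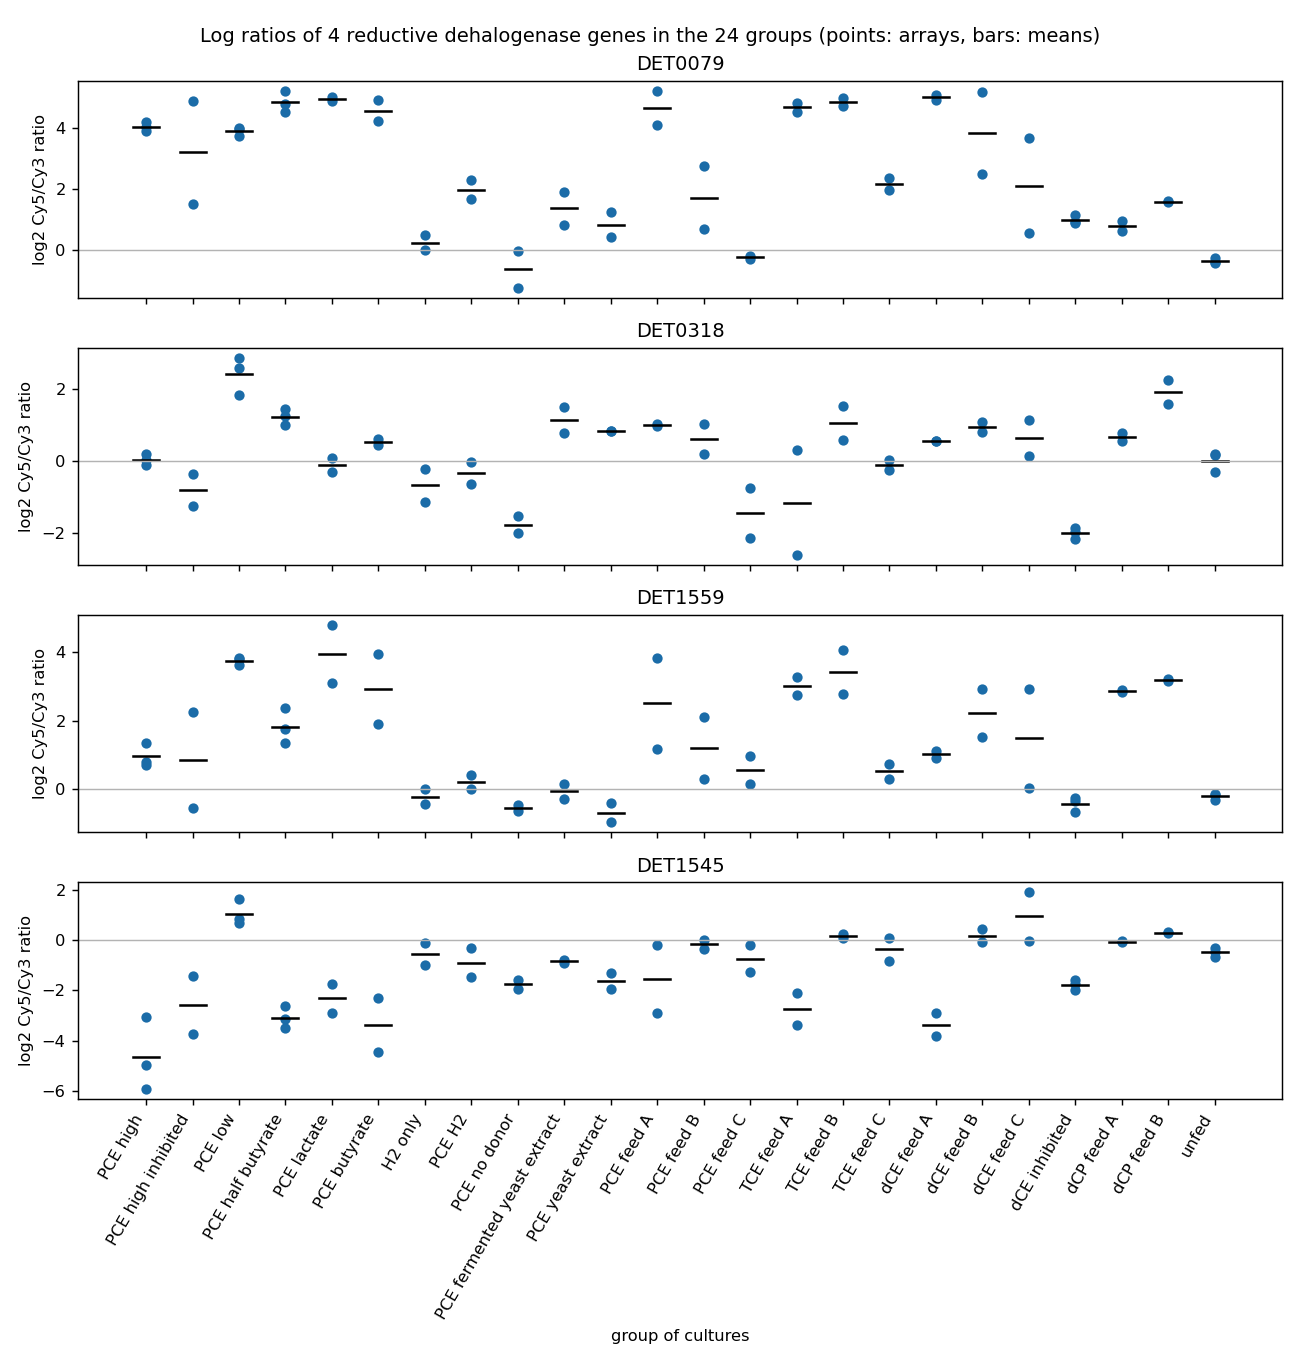
Log2 Cy5/Cy3 ratios of 4 reductive dehalogenase genes in the 24 groups, with a point per array and a bar at each group's mean. DET0079 has a mean of 3.93 in PCE low and 4.06 in PCE high, while DET1545 has 1.07 and −4.66, not well above background in PCE high.

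PCE feeds were set against unfed cultures (PCE fed vs unfed, 6 arrays against 3) to ask what feeding changes. The unfed arrays come from 2 decay series, per the labels, sampled after 96, 96 and 168 h, and were treated as replicates. DET0079 was at least 9.83-fold higher over the 3 feeds together (adjusted p = 0.00148; fitted log2 2.42, SE 0.57) and DET1559 at least 3.28-fold (adjusted p = 0.0473; fitted log2 1.63, SE 0.58), neither well above background on any unfed array. The mean of DET0079 in feed C, −0.25, was near the −0.37 of unfed cultures. DET0162 was 1.88-fold higher (log2 0.91, SE 0.27, adjusted p = 0.0145), well above background on 1 of 3 unfed arrays. With PCE low in place of the feeds DET0162 had 0.12 and was not called. The other 12 reductive dehalogenases did not pass, DET0318 with 0.05 (SE 0.39), although with PCE low in place of the feeds it had 2.42 and was called, and counts adjusted over the list alone were the same. DET0860 of Ech was lower (−1.93, SE 0.27, adjusted p = 1.56e-06), as was DET0929 of Nuo (−1.69, SE 0.24), while the other members of both lists did not pass. Of the 6 community members 2 were higher and 1 lower, 3 and 1 adjusted over the list alone. Outside the lists were DET1436 (3.48, SE 0.35; well above background on 1 of 3 unfed arrays), turning to −0.27 after scale normalization, and DET1475 (−3.80, SE 0.42). DCL2_Hyd_MvH1-MHU, not well above background in unfed cultures, was at least 7.62-fold higher (adjusted p = 0.000427), but on the log2 scale had −0.07 with PCE low in place of the feeds and −0.12 within slide 1. In total 55 genes were higher and 216 lower (405 unadjusted). The balance turned with the scaling, with 528 to 176 in the software's own ratios, 513 to 200 in the authors' table, 466 to 494 in Cy5 alone, 243 to 409 after scale normalization and 218 to 16 after median centring. A random block for slide left 184. DET1559 was no longer called without PCE feed A replicate 1 (1.19), PCE feed B replicate 2 (1.33), PCE feed C replicate 1 (1.50) or unfed replicate 1 (1.65), 2 (1.57) or 3 (1.67), and DET0162 without PCE feed A replicate 1 (0.70) or unfed replicate 1 (0.85) or 2 (0.82).

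PCE high and PCE low (3 arrays each) respired 130 to 170 and 6.2 to 6.7 µeeq per litre and hour, over 24 h and 168 h. Several reductive dehalogenases fell. DET0173 fell to 0.0183 of its level in PCE low (log2 −5.77, SE 0.60, adjusted p = 1.13e-08), well above background on 1 of 3 arrays of PCE high, and DET0180 to 0.0479 (−4.39, SE 0.50). DET1545, not well above background in PCE high, was at least 31.7-fold lower (adjusted p = 6.09e-08). DET0318 fell by 2.40 (SE 0.45, adjusted p = 4.28e-05) and DET1559 by 2.80 (SE 0.67). Of the list 8 passed downward, 1 of them (DET1522) not well above background in either group, and 1 rose, DET0162 by 2.40 (SE 0.32), the same adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.747 with an estimated correlation). DET0079 did not pass, at 4.06 ± 0.15 against 3.93 ± 0.14 (difference 0.14, SE 0.65, adjusted p = 0.863, interval −1.20 to 1.47). Of Hym 6 members rose and 1 fell, DET0145 by 2.33 (SE 0.50; −0.27 after scale normalization), and 8 of 11 Nuo members rose. In Ech 7 rose and 1 fell. All 3 formate dehydrogenase-like members rose, DET0187 by 1.63 (SE 0.45; −0.12 after scale normalization), and 2 of 3 Hup members, DET0111 by 1.41 (SE 0.44). DET0111 turned to −0.55 after scale normalization and to −0.07 with brightness in the model. Of the 6 community members 4 were higher and 0 lower in limma (median 0.70). Counts adjusted over the list alone were the same for these 6 lists. Outside the lists DET0476 rose by 5.16 (SE 0.60) and DET0765 fell by 5.87 (SE 0.91; well above background on 1 of 3 arrays of PCE high; 1.05 after scale normalization).

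In PCE high vs PCE low 548 genes were higher and 455 lower (1055 unadjusted), 221 and 292 by over 2-fold. PCE low lies on slide 1 of scan day 1 and PCE high on slides 5 and 6 of scan day 2, so slide and rate can be parted only through other groups. With slide as a block 5 genes were called (166 unadjusted), and DET0173 (−5.23), DET1545 (−5.42) and DET0180 (−3.31) were not among them. With brightness in the model 263 were called. Of the 837 genes that followed the rate in the feeds 650 were also called here, 644 in the same direction and 6 in the opposite one.

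Inhibited cultures (2 arrays, 168 h) were compared with uninhibited ones (PCE high inhibited vs PCE high). DET0137 was 108-fold higher (log2 6.76, SE 0.49, adjusted p = 6.65e-12) and DET0588 37-fold (5.21, SE 0.29), while DET1448 fell by 3.76 (SE 0.52). The reductive dehalogenase DET0173 passed upward (3.44, SE 0.67, adjusted p = 0.000201), well above background on 1 of 2 inhibited arrays and 1 of 3 others. DET1545 passed too (2.08, SE 0.74, adjusted p = 0.0238; −0.04 in Cy5 alone), but was not well above background in either group, so no difference can be read from it. Of the 15, 3 passed upward, DET1545 among them, so that 2 can be read as higher, and 1 fell (3 and 0 adjusted over the list alone). DET0079 did not pass (−0.85, SE 0.73, adjusted p = 0.358). Of 7 Hym members 4 fell, DET0145 by 2.76 (SE 0.55), and of 11 Nuo members 6, 7 adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.82 with an estimated correlation). DET0187 (−1.02, SE 0.50, adjusted p = 0.0961) and DET0111 (−0.44, SE 0.49) did not pass. Of the 6 community members 3 fell. In total 307 genes were higher and 377 lower (798 unadjusted), with 245 to 465 after median centring and 58 to 43 after scale normalization. With slide as a block 8 were called. DET1545 was no longer called without PCE high replicate 2 (1.93) or 3 (1.44) or PCE high inhibited replicate 1 (0.93). DET0079 (−2.55), DET0187 (−1.98) and DET0111 (−1.36) passed without PCE high inhibited replicate 2. The count was 406 without PCE high replicate 3 and 258 without PCE high inhibited replicate 1.

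dCE inhibited cultures (3 arrays, 168 h, 35 to 39 µeeq per litre and hour) were compared with 2 arrays (dCE inhibited vs dCE feed A). DET0079 fell to 0.0605 of its level (log2 −4.05, SE 0.73, adjusted p = 4.58e-05) and DET0318 to 0.169 (−2.56, SE 0.50). DET0180 was higher (2.04, SE 0.56). DET0173 passed upward (1.95, SE 0.67, adjusted p = 0.0141; −0.70 after scale normalization), but was well above background on no inhibited array and on 1 of 2 of feed A, so no fold can be given. Of the reductive dehalogenases 2 besides DET0173 rose and 2 fell. All 3 Hup members fell, DET0112 by 3.13 (SE 0.49, adjusted p = 8.22e-06) and DET0111 by 2.06 (SE 0.49), and all 3 formate dehydrogenase-like members, DET0187 by 2.60 (SE 0.50). Of Nuo 10 of 11 fell (camera adjusted p = 0.0226, adjusted p = 0.844 with an estimated correlation). Of Hym 6 of 7 fell, 7 adjusted over the list alone, DET0145 by 3.05 (SE 0.55; camera adjusted p = 0.0052, adjusted p = 0.747 with an estimated correlation). Of Ech 7 fell and 1 rose, and 3 of 6 community members fell. Counts adjusted over the list alone were otherwise the same. Outside the lists DET1412 rose by 4.73 (SE 0.76) and DET0650 fell by 5.79 (SE 0.68). In total 429 genes were higher and 452 lower (975 unadjusted). With slide as a block 84 were called, DET0173 (0.09) and DET0180 (0.13) not among them. DET0173 was no longer called without dCE feed A replicate 2 (1.58), nor DET0180 without dCE feed A replicate 1 (1.36).

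Donors were compared in cultures respiring PCE. With lactate (2 arrays) against butyrate (2 arrays) 38_DCL2_Nitrospira_sp1 was 110-fold higher (log2 6.78, SE 0.53, adjusted p = 5.27e-11; 7.21 ± 0.30 against 0.43 ± 0.64) and 9_DCL2_Nitrospira_sp2 37.8-fold (5.24, SE 0.38). The Syntrophomonas probes 13_DCL2_Syntrophomonas_sp2 (−2.22, SE 0.53, adjusted p = 0.0271) and 11_DCL2_Syntrophomonas_sp (−1.87, SE 0.47, adjusted p = 0.0393) were lower. They are the 2 of 6 community members that fell, against 1 higher and 2 lower adjusted over the list alone (camera on these 2 probes alone, adjusted p = 0.000307, adjusted p = 0.138 with an estimated correlation). Of D. mccartyi DET0871 fell by 2.40 (SE 0.47), and no listed reductive dehalogenase or hydrogenase passed, DET0079 with 0.38 (SE 0.80, interval −1.25 to 2.02). In total 13 genes were higher and 3 lower (112 unadjusted), with 12 to 5 in Cy5 alone. 9_DCL2_Nitrospira_sp2 was weaker in 4 of 16 settings (lowest 0.32). Within slide 3, with 2 arrays against butyrate replicate 2, 10 genes were called. The count was 10 and 6 without lactate replicates 1 and 2, and 10 and 148 without butyrate replicates 1 and 2. Both Syntrophomonas probes were no longer called without lactate replicate 1 (−2.19 and −1.94) or 2 (−2.25 and −1.81) or butyrate replicate 1 (−2.07 and −1.86), nor DET0871 without lactate replicate 2 (−2.29) or butyrate replicate 1 (−1.65).

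PHB, the labels' short name for cultures on PCE with less butyrate (3 arrays), gave against butyrate 32 genes higher and 13 lower (242 unadjusted). Respiration was 85, 39 and 97 µeeq per litre and hour in PHB against 30 and 54 with butyrate, so rate differs as well. The ratio of donor to acceptor was 0.73, 1.7 and 0.72 against 1.5 and 1.8, so PHB replicate 2 lies in the range of butyrate. 30_DCL2_Sulfuricurvum.sp.(Epsil... was 6.44-fold higher (log2 2.69, SE 0.27, adjusted p = 7.55e-08), 9_DCL2_Nitrospira_sp2 5.13-fold (2.36, SE 0.34, adjusted p = 0.000169), and DET0871 fell by 1.56 (SE 0.43, adjusted p = 0.0369). No listed reductive dehalogenase or hydrogenase passed, DET0079 with 0.28 (SE 0.73, interval −1.21 to 1.78). Of the 6 community members 1 fell, 4 adjusted over the list alone. The split was 31 to 4 in the software's own ratios, 9 to 15 in Cy5 alone and 2 to 2 after median centring. Within slide 3 the count was 21, without PHB replicate 2 it was 16, and without butyrate replicates 1 and 2 it was 21 and 213. DET0871 had −0.80 without butyrate replicate 1, and −1.63, −1.44 and −1.59 without PHB replicates 1, 2 and 3, none called.

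PCE with hydrogen as donor (PCE H2, 2 arrays, 36 h, 7.3 and 9.7 µeeq per litre and hour) was compared with 3 arrays of 168 h (PCE H2 vs PCE low). DET1559 fell to 0.0855 of its level (log2 −3.55, SE 0.75, adjusted p = 0.00314) and DET0318 to 0.147 (−2.77, SE 0.50, adjusted p = 0.000683). With PCE feed B as comparator neither passed (−0.98 and −0.94). These are 2 of 15 reductive dehalogenases, against 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000168, adjusted p = 0.136 with an estimated correlation). DET0079 (−1.95, SE 0.73, adjusted p = 0.126) and DET0111 (−0.14, SE 0.49) did not pass, and DET0765 was 12-fold higher (3.58, SE 1.01, adjusted p = 0.0311). Of the 6 community members 2 were higher, 5 adjusted over the list alone. In total 55 genes were higher and 27 lower (250 unadjusted), with 188 to 160 in the authors' table, 132 to 145 in Cy5 alone, 212 to 170 after scale normalization and 32 to 2 after median centring. A random block for slide left 19. The count was 30 without PCE low replicate 2 and 20 without PCE H2 replicate 2. DET0765 was no longer called without PCE low replicate 2 (3.32) or 3 (3.56) or PCE H2 replicate 1 (3.30) or 2 (3.87).

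PCE H2 was also set against hydrogen without acceptor (H2 only, 2 arrays) to part the acceptor from the donor (PCE H2 vs H2 only). DET1360 was 11.4-fold higher with PCE (log2 3.51, SE 0.40, adjusted p = 1.02e-06). DET0079 (1.98 ± 0.44 against 0.24 ± 0.34; difference 1.74, SE 0.80, adjusted p = 0.354) and DET0111 (0.72, SE 0.53) did not pass. No member of the community list passed over all genes and 1 adjusted over the list alone, lower (camera adjusted p = 0.026, adjusted p = 0.747 with an estimated correlation). The set test rests on 2 of the 6 members, and the list's median was 0.08. In total 8 genes were higher and 12 lower (194 unadjusted), with 277 to 204 in the software's own ratios, 250 to 216 in the authors' table and 1 to 0 after median centring. Blocking by slide gave 46, and 38 were called without the array of dark reference. The count was 11 without H2 only replicate 1, and 56 and 2 without PCE H2 replicates 1 and 2. H2 only vs unfed (3 arrays) had 33 genes higher and 120 lower (234 unadjusted), DET0954 by 3.44 (SE 0.63; well above background on 1 of 3 unfed arrays) and DET0307 by −3.37 (SE 0.48), while DET0079, not well above background in unfed cultures, did not pass (0.61, SE 0.73). The balance was 398 to 42 in the software's own ratios, 399 to 48 in the authors' table, 265 to 305 in Cy5 alone and 86 to 0 after median centring. With slide as a random block 104 were called, and 77 and 97 without H2 only replicate 2 and unfed replicate 2.

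Yeast extract and fermented yeast extract (2 arrays each) carried PCE respiration of 4.1 to 4.9 µeeq per litre and hour, PCE low 6.2 to 6.7. In yeast extract vs PCE low, 8 of 15 reductive dehalogenases passed downward with yeast extract, 1 of them (DET1522) not well above background in PCE low, the same adjusted over the list alone (camera adjusted p = 0.000168, adjusted p = 0.136 with an estimated correlation). DET1559 fell to 0.0456 of its level (log2 −4.45, SE 0.75, adjusted p = 0.000406), DET0180 to 0.0983 (−3.35, SE 0.56), DET0079 to 0.117 (−3.10, SE 0.73, adjusted p = 0.00784) and DET1545 to 0.157 (−2.67, SE 0.74, adjusted p = 0.0223). DET0318 fell by 1.60 (SE 0.50, adjusted p = 0.0441), but had 0.22 with PCE feed B as comparator. With that comparator DET1559 (−1.89) and DET0079 (−0.90) no longer passed. In total 85 genes were higher and 49 lower (319 unadjusted), with 96 to 85 in the software's own ratios, 92 to 93 in the authors' table and 285 to 60 after median centring. Blocking by slide left 124. DET0079 was no longer called without yeast extract replicate 2 (−2.69), nor DET1545 without PCE low replicate 1 (−2.37) or yeast extract replicate 1 (−2.99) or 2 (−2.35), nor DET0318 without PCE low replicate 2 (−1.38) or 3 (−1.52) or yeast extract replicate 1 (−1.61) or 2 (−1.59). The count was 57, 70 and 84 without PCE low replicates 1, 2 and 3, and 55 and 13 without yeast extract replicates 1 and 2.

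In yeast extract vs fermented yeast extract 2 genes differed, both higher with unfermented yeast extract (89 unadjusted): 23_D2CL_Eubacterium.sp._A, a community probe (log2 1.69, SE 0.36, adjusted p = 0.0369), and DET0711 (0.84, SE 0.16, adjusted p = 0.0155). Neither was called without yeast extract replicate 1 (2.07 and 0.78) or 2 (1.31 and 0.90) or fermented yeast extract replicate 1 (1.58 and 0.72), and 23_D2CL_Eubacterium.sp._A not without fermented yeast extract replicate 2 (1.81). The count was 0 without fermented yeast extract replicate 1 or yeast extract replicate 1 or 2. With scale normalization 1 was higher and 9 lower, and in Cy5 alone 0 were called in limma (36 unadjusted).

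PCE without donor (2 arrays, 72 h) was compared with 2 arrays of the slowest feed (no donor vs PCE feed C). DET1005 was 11.6-fold higher without donor (log2 3.53, SE 0.29, adjusted p = 4.47e-10; well above background on 1 of 2 arrays of PCE feed C), and DET1349 fell by 3.27 (SE 0.56, adjusted p = 0.000281). DCL2_Hyd_MvH1-MHU, not well above background without donor, was at least 23.4-fold lower (adjusted p = 0.00576), but was not called without PCE feed C replicate 1 (−1.57) or no donor replicate 2 (−3.64). No listed reductive dehalogenase or hydrogenase passed, DET0187 (adjusted p = 0.387) being well above background on 1 of 4 arrays alone. In total 33 genes were higher and 26 lower (264 unadjusted), with 23 to 28 in Cy5 alone, 47 to 56 in the authors' table and 5 to 6 after median centring. With slide as a random block 26 were called, and 29 without the array of dark reference. The count was 34 and 14 without no donor replicates 1 and 2, and 24 without PCE feed C replicate 2.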

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

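The tests of changes in inhibited cultures were chosen after the results were seen; the F test of slopes was set before. Both acceptors were followed into inhibited cultures, and the change differed between them for 311 genes (limma; 463 at an unadjusted p under 0.05). Without PCE high inhibited replicate 1 it was 343 genes and without replicate 2 it was 191. The difference is the change with PCE (inhibited minus PCE high, 2 and 3 arrays) minus that with dCE (inhibited minus feed A, 3 and 2 arrays). DET0079 (tceA) differed by 3.20 on the log2 scale (SE 1.03, adjusted p = 0.0278), having changed by −0.85 with PCE and by −4.05 with dCE. DET0186 differed by 2.58 (SE 0.81, adjusted p = 0.0232) and DET0110 (hupL) by 2.27 (SE 0.64, adjusted p = 0.0118). In both the fall was larger with dCE, −3.49 against −0.90 for DET0186 and −2.50 against −0.23 for DET0110. The neighbouring tags DET0728, DET0729 and DET0730 differed by 0.69, 0.98 and 0.92 (adjusted p = 0.0374, 0.00732 and 0.00348). DET0162 went the other way, by −1.57 (SE 0.50, adjusted p = 0.0251). Of these 7 genes only DET0730 kept its call without each array. Without PCE high inhibited replicate 2, DET0079 differed by 1.50 (adjusted p = 0.37), DET0186 by 1.29 (0.32), DET0110 by 1.94 (0.0809), DET0728 by 0.77 (0.0617) and DET0729 by 0.71 (0.0956). Without replicate 1, DET0079 had 4.90 and DET0186 3.88, both called, while DET0162 (−1.23, adjusted p = 0.119) and DET0728 (0.62, 0.105) were not. DET0079 was not called without PCE high replicate 3 (3.12) or dCE feed A replicate 1 (3.13) or 2 (3.27), DET0162 without PCE high replicate 3 (−1.46) or dCE feed A replicate 1 (−1.23), and DET0186 without dCE feed A replicate 2 (2.44). DET0728 was not called either without PCE high replicate 2 (0.64) or 3 (0.66), dCE feed A replicate 2 (0.51) or dCE inhibited replicate 2 (0.67) or 3 (0.67). Of all genes 32 were called in both comparisons with opposite signs. The comparators differ in rate, 130 to 170 µeeq per litre and hour in PCE high against 18 and 32 in dCE feed A, and lie on other slides than the inhibited cultures. Duration differs too, 168 h in inhibited cultures against 24 h in PCE high and 96 and 48 h in dCE feed A. Acceptor, rate, duration and slide therefore cannot be told apart here.

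Some genes moved in opposite directions between feeds A and C, every array of one acceptor going one way and every array of another the opposite way. These differences were not tested. DET0180, a reductive dehalogenase, was higher by 0.76 in feed A than in feed C with PCE, but lower with TCE (−1.86) and dCE (−2.16), 2 arrays each. DET0728 was lower with PCE (−0.26) and TCE (−0.67) and higher with dCE (0.35). DET0927 was lower with PCE (−0.14) and higher with dCE (0.36). In PCE feed C neither DET0180 nor DET0927 was well above background on any array. The limma F test of slopes differing between acceptors called 0 of 1551 genes (109 at an unadjusted p under 0.05). Groups of 2 or 3 arrays are too small for a check for single arrays far from the others.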

How the results depend on the processing

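The tests without the arrays of dark reference, with Cy5 brightness as covariate, in feed A alone, within slides 1 and 3 and against PCE H2 of the same slide were chosen after the data were seen; the others were set before. With no filter on dim probes all 21 counts of called genes stayed within 1.5 times those reported, as did 20 with a strict filter and 20 with a block for replicate number. All 135 gene values reported kept direction and side of the threshold without a filter, and 130 with the replicate block. The software's own ratios kept 115 of them and the authors' ratios 116. Cy5 alone kept 115, median centring 85, scale normalization 61 and brightness as covariate 94. The slide block kept 57 of 115, the arrays of the groups compared alone 69 of 115, and log2 rate as covariate 8 of 20, the other 12 being weaker. Without 1 array each, 1093 of 1215 values were kept and 0 reversed. The cause was not tested for any moved value below unless one is given.

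Counts that moved by more than 1.5 times are given by setting, as limma calls. With the software's own ratios they were 561 for feed B vs feed C, 529 for feed A vs feed B, 9 for the bend of the rate response, 8 for dCE vs TCE, 329 for dCP vs PCE feed C, 704 for PCE fed vs unfed, 9 for lactate vs butyrate, 369 for PCE H2 vs PCE low, 481 for PCE H2 vs H2 only, 0 for yeast extract vs fermented yeast extract (47 at an unadjusted p under 0.05), 106 for no donor vs PCE feed C and 440 for H2 only vs unfed. The authors' log ratio table gave, in the same order, 522, 553, 5, 14, 321, 713, 9, 348, 466, 0 (45 unadjusted), 103 and 447. With median centring they were 449 for the rate slope, 1 for feed B vs feed C, 140 for TCE vs PCE, 0 for dCE vs TCE (134 unadjusted), 28 for dCP vs PCE feed C, 4 for PHB against butyrate, 34 for PCE H2 vs PCE low, 1 for PCE H2 vs H2 only, 1 for yeast extract vs fermented yeast extract, 345 for yeast extract vs PCE low, 11 for no donor vs PCE feed C and 86 for H2 only vs unfed. Cy5 alone gave 289 for feed B vs feed C, 11 for the bend of the rate response, 570 for dCE vs PCE, 50 for dCE vs TCE, 262 for dCP vs PCE feed C, 960 for PCE fed vs unfed, 24 for PHB against butyrate, 277 for PCE H2 vs PCE low, 536 for PCE H2 vs H2 only, 0 for yeast extract vs fermented yeast extract (36 unadjusted) and 570 for H2 only vs unfed. The strict filter gave 3 for the bend of the rate response.

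Scale normalization between arrays gave 440 for the rate slope, 455 for feed B vs feed C, 79 for the bend of the rate response, 537 for dCE vs PCE, 6 for dCE vs TCE, 240 for dCP vs PCE feed C, 652 for PCE fed vs unfed, 500 for PCE high vs PCE low, 101 for PCE high inhibited vs PCE high, 543 for dCE inhibited vs dCE feed A, 3 for lactate vs butyrate, 0 for PHB against butyrate (48 unadjusted), 382 for PCE H2 vs PCE low, 529 for PCE H2 vs H2 only, 10 for yeast extract vs fermented yeast extract, 103 for no donor vs PCE feed C and 246 for H2 only vs unfed. By construction it multiplies the ratios of arrays with a small spread, which the 4 arrays of dark reference have. It turned DET0173 to 0.00896 (rate slope) and −0.70 (dCE inhibited vs dCE feed A). In feed A vs feed B it turned DET0079 to −10.60 and DET0111 to −0.13. In TCE vs PCE it turned DET0079 to −17.86, DET0111 to −0.84, DET0297 to −1.82 and 11_DCL2_Syntrophomonas_sp to −0.51, and in dCE vs PCE the first 3 to −17.73, −0.76 and −0.75. DET1436 turned to −0.27 in PCE fed vs unfed. In PCE high vs PCE low DET0145 turned to −0.27, DET0187 to −0.12, DET0111 to −0.55 and DET0765 to 1.05.

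Other reversals were DET1545 in PCE high inhibited vs PCE high with Cy5 alone (−0.0358), DET0111 in PCE high vs PCE low with brightness (−0.0685) and DET0318 in yeast extract vs PCE low with PCE feed B as comparator (0.22). The value of DCL2_Hyd_MvH1-MHU PCE fed vs unfed turned with PCE low (−0.0745) and within slide 1 (−0.115), and that of DCL2_Hyd_MvH1-MHU dCP vs PCE feed C with PCE H2 as comparator (0.20).

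A block for replicate number gave 1 for the bend of the rate response.

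Slide blocks were fixed where groups shared between slides allow it and otherwise random (correlation 0.227). Fixed blocks gave 6 for the bend of the rate response, 5 for PCE high vs PCE low, 8 for PCE high inhibited vs PCE high, 84 for dCE inhibited vs dCE feed A, 8 for lactate vs butyrate, 13 for PHB against butyrate, 46 for PCE H2 vs H2 only, and 1 for yeast extract vs fermented yeast extract. Random blocks gave 14 for TCE vs PCE, 6 for dCE vs PCE, 16 for dCP vs PCE feed C, 19 for PCE H2 vs PCE low and 26 for no donor vs PCE feed C. On the arrays of the groups compared alone, with fewer arrays to estimate the spread, limma gave 0 for feed B vs feed C (277 unadjusted), feed A vs feed B (318), dCE vs TCE (79), lactate vs butyrate (58), PHB against butyrate (174), PCE H2 vs H2 only (133), yeast extract vs fermented yeast extract (422), no donor vs PCE feed C (374) and H2 only vs unfed (194). It gave 142 for TCE vs PCE, 12 for dCE vs PCE, 125 for PCE fed vs unfed, 74 for PCE high inhibited vs PCE high and 483 for yeast extract vs PCE low. With log2 rate as covariate on the 18 feed arrays the counts were 103 for TCE vs PCE, 45 for dCE vs PCE and 0 for dCE vs TCE (80 unadjusted). For dCP vs PCE feed C they were 134 against the mean of the feed C groups and 152 against PCE H2. With PCE feed B as comparator PCE H2 vs PCE low gave 8. Within slide 3 lactate vs butyrate gave 10 and PHB against butyrate 21.

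Without the arrays of dark reference feed B vs feed C gave 55, feed A vs feed B 169, the bend of the rate response 2, PCE H2 vs H2 only 38, no donor vs PCE feed C 29 and H2 only vs unfed 85. Brightness as covariate gave in limma 0 for the rate slope (352 unadjusted), 33 for feed B vs feed C, 62 for feed A vs feed B, 4 for the bend of the rate response, 168 for TCE vs PCE, 70 for dCE vs PCE, 7 for dCE vs TCE, 263 for PCE high vs PCE low, 315 for PCE high inhibited vs PCE high, 142 for PCE H2 vs PCE low, 8 for PCE H2 vs H2 only, 1 for yeast extract vs fermented yeast extract and 334 for yeast extract vs PCE low. In feed A alone TCE vs PCE gave 65, dCE vs PCE 177 and dCE vs TCE 55. Of 160 set tests over the 8 lists, 21 were called with the preset correlation and 0 with an estimated one.

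Leaving out each array in turn gave 670 to 914 for the rate slope, 1 to 454 for feed B vs feed C, 16 to 642 for feed A vs feed B, 0 to 10 for the bend of the rate response, 0 to 1 for the acceptor by rate interaction, 188 to 654 for TCE vs PCE, 100 to 714 for dCE vs PCE, 1 to 56 for dCE vs TCE, 20 to 105 for dCP vs PCE feed C, 189 to 401 for PCE fed vs unfed, 824 to 1036 for PCE high vs PCE low, 258 to 794 for PCE high inhibited vs PCE high, 641 to 801 for dCE inhibited vs dCE feed A, 6 to 148 for lactate vs butyrate, 16 to 213 for PHB against butyrate, 20 to 76 for PCE H2 vs PCE low, 2 to 56 for PCE H2 vs H2 only, 0 to 2 for yeast extract vs fermented yeast extract, 13 to 84 for yeast extract vs PCE low, 14 to 59 for no donor vs PCE feed C and 77 to 200 for H2 only vs unfed. Where a group was left with 1 array, that array was assumed to vary like the other groups. The arrays behind these moves are named with the comparisons.

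Scaling also shifted the median log2 difference of all genes by more than 0.1. In the software's own ratios it was 0.21 for dCE vs PCE, 0.16 for dCE vs TCE, 0.42 for PCE fed vs unfed, 0.42 for PCE high vs PCE low, −0.22 for PCE high inhibited vs PCE high, −0.15 for dCE inhibited vs dCE feed A, 0.26 for PHB against butyrate, 0.22 for PCE H2 vs PCE low, 0.30 for PCE H2 vs H2 only and 0.15 for yeast extract vs PCE low. In the authors' log ratio table it was 0.18 for dCE vs PCE, 0.12 for dCE vs TCE, 0.32 for PCE fed vs unfed, 0.37 for PCE high vs PCE low, −0.18 for PCE high inhibited vs PCE high, −0.15 for dCE inhibited vs dCE feed A, 0.20 for PHB against butyrate, 0.15 for PCE H2 vs PCE low and 0.20 for PCE H2 vs H2 only. With median centring it was 0.12 for PCE fed vs unfed, 0.20 for yeast extract vs PCE low, 0.39 for PCE high vs PCE low and −0.35 for PCE high inhibited vs PCE high. Changes in these comparisons are relative to the centre of all genes. A choice of the brightest probe per gene was not run, since each gene has 1 probe name, and the acceptor by rate interaction was not run with slide or brightness.

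Signal over background limits dim genes and arrays: the offset pulls them toward 0.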

Other observations

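The gene lists, the pairs of genes and the tests of dim arrays, of other cultures, of slide, of rate as covariate and of gene pairs were chosen after the data were seen; the tests of brightness, of leaving out 1 slide and of other splits were set before their results. Of 41 tRNA probes 26 fell with the rate in the feeds and 3 rose (median slope −0.21 per doubling; camera adjusted p = 3.48e-05, adjusted p = 0.72 with an estimated correlation). In PCE fed vs unfed 24 were lower and 1 higher (median −1.16; 9.73e-07; adjusted p = 0.575 with an estimated correlation), and in PCE H2 vs PCE low 12 were higher and 1 lower (median 1.06; 9.96e-15; adjusted p = 0.396 with an estimated correlation). In PCE high vs PCE low, also a difference in rate, 12 were higher and 8 lower (median −0.05; 0.719). Of the 13 protein loci with the most spots, 8 rose with the rate and 1 fell (0.00453; adjusted p = 0.575 with an estimated correlation), and 9 fell in dCE inhibited vs dCE feed A.

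Of 40 clone probes of the community, in H2 only vs unfed 10 were higher and 7 lower (median 0.36; camera adjusted p = 2.44e-06; adjusted p = 0.396 with an estimated correlation). In dCP vs PCE feed C 8 were higher and 2 lower (median 0.40; 3.48e-05; adjusted p = 0.398 with an estimated correlation), and in yeast extract vs fermented yeast extract 1 was higher (median 0.39; 0.00351; adjusted p = 0.575 with an estimated correlation), while in PCE H2 vs H2 only 3 were lower and 0 higher (median −0.50; 2.14e-11; adjusted p = 0.189 with an estimated correlation). The set tests of these clone probes rest on 18 of the 40. Probes of Syntrophomonas were lower with lactate in 2 of 5 (6.58e-05; adjusted p = 0.189 with an estimated correlation), a set test of 2 probes. Of the 5 probes ending in MHU, 3 were lower with TCE than with PCE (0.00515; adjusted p = 0.398 with an estimated correlation) and 3 with dCE (0.000532; 0.396). Of 3 ribosomal RNA probes of D. mccartyi 2 were higher without donor than in PCE feed C (0.00687; adjusted p = 0.398 with an estimated correlation). Clone probes of methanogens were not tested. On scan day 1 (23 arrays) the median Cy5 signal of protein genes varied 57.5-fold between arrays, and that of 16S rRNA 1.96-fold.

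Many genes follow the respiration rate. If shrinkage by the offset made the slopes, they should be lost without offset and dark arrays. Of 837 genes 744 (88.9%) kept call and direction, which argues against it. Kept were 150 of 167 probes well above background in both channels and 594 of 670 others. Arrays dim in Cy5 stayed in, so other compression was not tested. For direction a single slide is argued against. Of genes called on 2 slides, 95.6% had the same direction on the PCE slide left out (680 of 711). On the dCE slide it was 98.1% (511 of 521). Without the TCE slide only 8 genes were called, all with its direction, so calls lean on that slide. In PCE high vs PCE low 94.5% of the 837 genes had the same direction (791). Slide, scan day and Cy5 brightness (mean 799 against 40) differ there too. Brightness stays open. The bound set in advance was over 80% keeping direction with brightness in the model, and 100% did (837 of 837). That bound was wrong, since the genes were chosen by their slope, which nearly fixes the direction. With brightness in the model 0 of the 837 stayed called in limma (336 unadjusted). The median slope size went from 0.179 to 0.107 and its SE from 0.0481 to 0.0541. The calls ended mainly with the fall of the slopes, since the SE rose little. The brightness term had the sign of the slope in 825 of 837 genes, and was itself called for 0 in limma (527 unadjusted). A change of mRNA per cell with respiration or a technical difference in labelled cDNA that bends ratios may explain both. They cannot be told apart here.

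PCE feeds differ from TCE and dCE feeds. Mean log2 rates in TCE and dCE feeds were 0.476 and 0.714 above those in PCE feeds. Whether this difference in rate is the whole cause was asked with rate as a covariate. On the 18 feed arrays, with log2 rate added to acceptor in the model, the median size of the 417 reported differences in TCE vs PCE went from 0.738 (SE 0.278) to 0.649 (SE 0.218), 87.9%. For the 352 in dCE vs PCE it went from 0.781 (SE 0.323) to 0.634 (SE 0.251), 81.2%. All kept their direction and over 50% of their size. Few passed on these arrays alone, 43 of 417 and 19 of 352 without rate and 100 and 43 with it, and of 20 reported gene values 8 kept direction and side of the threshold with rate and 12 were weaker. Slide stays open: each acceptor has a slide of its own, and with slide as a random block 2.6% of calls were left (20 of 769). The acceptor may act on expression, as the design proposes, but slide and acceptor cannot be told apart. DCL2_Hyd_MvH1-MHU, high on some arrays of slide 4 alone, is a value that a slide or a culture batch may explain as well.

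Genes of the Hup hydrogenase and of DET0186 to DET0187 move together over the 24 groups. DET0111 and DET0187 correlated with r = 0.974 and rho = 0.961 (permutation p = 1e-05 for both, the smallest the permutations can give; adjusted 1.2e-05 over 6 pairs; r = 0.972 without the 2 farthest groups), and DET0112 and DET0186 with 0.956 and 0.95 (1e-05; adjusted 1.2e-05; r = 0.952 without 2). DET0185, next to DET0186, correlated with DET0187 with only r = 0.776 and rho = 0.656 (permutation p = 1e-05 and 0.00051; adjusted 1.2e-05 and 0.00051; r = 0.791 without 2). With DET0931 of the Nuo complex it had r = 0.936 and rho = 0.796 (1e-05; adjusted 1.2e-05; r = 0.901 without 2). DET0924 had r = 0.838 and rho = 0.852 with DET0111 (1e-05; adjusted 1.2e-05; 0.828 without 2) and 0.784 and 0.788 with DET0931 (2e-05 and 1e-05; adjusted 2e-05 and 1.2e-05; 0.766 without 2). With rate taken out over 21 groups the r of the first pair was 0.935, at percentile 99.8 of 10000 random pairs among 427 genes (median 0.501, 95th percentile 0.837). The pair was picked after its values were seen, so this percentile does not decide whether it differs from other genes that follow the rate. Brightness shared by all genes of an array stays in these values. Groups within a slide are not independent.

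Other splits of the same arrays asked whether chance can be excluded, each in a fit on those arrays alone, for the feeds with acceptor or feed level as covariate. For feed B vs feed C and feed A vs feed B this decides nothing: the real split gave 0 genes in limma (277 and 318 at an unadjusted p under 0.05 with a mean per group), and any split gives as many (100 of 100, the highest others 605 and 455). The highest split in feed A vs feed B puts the brighter Cy5 arrays on one side, with TCE feed B replicate 2 in place of PCE feed A replicate 2, a structure of the samples. For TCE vs PCE chance can be excluded (164 genes, highest other 5; 1 of 100 splits), as for dCE vs PCE (42 genes, highest other 1; 1 of 100) and PCE fed vs unfed (150 genes, highest other 7; 1 of 84). These splits follow slides too. For dCE vs TCE chance cannot be excluded (1 gene, highest other 33; 5 of 100 splits). PCE high vs PCE low has only 10 splits, too few for a share under 0.05 (981 genes, highest other 0).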
